A study of Mus musculus with 6 samples.

How the data were processed

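Total RNA from the spinal cords of 8-week-old male C57BL/6 mice was labelled with a single dye (Cy3) and hybridised to Agilent whole mouse genome arrays, 1 array per sample, in 3 wild-type and 3 Dhtkd1 null samples. Groups, replicate numbers, age, sex and strain were taken from the labels. The labels number the replicates but do not say in so many words that each is a separate animal, and they give no pairing of wild-type with null samples. P-values of single genes here measure the spread between the samples as labelled. Those of camera at a preset correlation, Fisher's exact test and shuffles set genes against other genes and do not measure that spread.

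The deposited scanner files hold the intensity of each spot, as made by Agilent Feature Extraction 10.7.3.1 on array design 014868, whose spots are placed on the mm9 mouse genome. Per the file headers, the processed intensity is background-subtracted and detrended within each array and is not normalized between arrays. The deposited table of values is in log2 units, for which the authors' method is not stated. Its columns have the same quantiles (medians of 7.22), and each follows the log2 processed intensity of its own array with r of 0.9997 or more across probes, so it was read as quantile normalized log2 intensity. That table served as an alternative only.

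Signals were taken as log2 of the processed intensity minus the 75th percentile of the array over its non-control probes. Spots marked as outliers by the scanner software (58 to 89 non-control spots per array) were left out, and repeated spots of a probe were averaged on the log2 scale. Each array held 43379 non-control spots of 41174 probes. Current gene symbols were given to 27668 probes through their accession in the reference table (assembly GRCm38.p6), 5589 probes already carried a current symbol, 471 were named through a synonym, and 7446 kept the name in the file, which gave 27343 different names, and 2314 printed names differ from those in the files. Probe positions are those of the files (mm9). Probes were not realigned, and a genome sequence was not used here. A probe was kept when it was well above background on at least 3 of the 6 arrays, which left 33190 probes, and each gene name was represented by its kept probe with the highest mean over all 6 arrays, which left 21438 genes.

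The only comparison was Dhtkd1 null minus wild-type. It was fitted with limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3, with no covariate and with Benjamini-Hochberg adjustment over all genes tested. Differences are log2 differences of group means with the moderated standard error (SE) and 3 samples per group, and standard deviations (SD) are between arrays of a group. A gene passed at an adjusted p under 0.05. A count at an unadjusted p under 0.05 with at least a 2-fold difference is given beside it. A gene that was well above background on no array of a group is given with a lower bound on its fold difference. For each array of that group, the bound takes the higher of the gene's own signal and the array's lowest signal well above background. An exact 2-sided permutation test of 3 against 3 arrays cannot give a p under 0.1.

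Genes were tested in 36 lists of pathways, cell states, cell types and loci with camera at a preset inter-gene correlation of 0.01, adjusted over the 36 lists, with Dhtkd1 itself left out. The same lists were tested with a correlation estimated from the arrays and with fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. A list's median is over its tested genes, and its array mean is the mean over the list of each gene's signal minus that gene's mean over all 6 arrays. The lists, the tests, the thresholds, the rule for naming genes and all but 1 of the alternatives were fixed before the data were examined. The rule named Dhtkd1, then up to 12 genes per direction among those past the adjusted threshold with non-overlapping groups, filled up to 12 with the genes of smallest unadjusted p that had non-overlapping groups and a log2 difference of at least 0.585 in size. Clone-like and predicted gene names were left out of that ranking. From each list it named the members past the adjusted threshold (at most 6), or else the 2 members of smallest p, and it named Dhtkd1 neighbours at an unadjusted p under 0.05. Other list members are given only as examples of a list. Some genes that the rule named are not reported.

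The barcodes in the file headers show 2 slides. Slide 1 holds wild-type replicate 2 and null replicates 1, 2 and 3, and slide 2 holds wild-type replicates 1 and 3. The slides were also scanned in that grouping. Slide was therefore tried as a fixed block and as a random block, and slide 1 was also used alone. The other alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, the authors' value table, no filter on dim probes, a filter on all 6 arrays, outlier spots kept, the mean of a gene's probes, each probe on its own, replicate number as a block, array weights, eBayes with trend and robust options, an adjusted p threshold of 0.1, and each array left out in turn. An added alternative, chosen after the data were seen, left out the 2 arrays at the ends of the first principal component. The procedure was tested on simulated data with 21434 genes drawn independently in 5 simulations. It recovered 65.2% of genes changed by a log2 of 1 and 87.8% of those changed by 2, with 56 false calls in all, called 10 of 10 lists shifted by 0.4 and called 0 of 155 lists that were not shifted. Real genes are correlated, which those simulations leave out.

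Precision is limited by the number of arrays. Of the spots of each array, 78.4% to 82.0% were well above background, 0 were saturated, and repeated probes had a median coefficient of variation of 3.91% to 4.29%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and version 1.17.8 of the R package data.table were used for reading, tables and plots. List genes with no probe on the array, which are not analysed here, include Pdp2, Irs2, Pck1, Crh, Zbtb16, Trpv1, Mrgprd, Prdm12, Tmem233, Hbb-b2 and Hbb-bs, and the signal that the files call Hbb-b1 is given here as Hbb-bt. The part of Dhtkd1 that was deleted is not stated in the labels or files.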

Results

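Gene expression was measured in the spinal cord of 8-week-old male mice, in 3 wild-type and 3 Dhtkd1 null samples with 1 array each. Dhtkd1 encodes a subunit of a mitochondrial 2-oxoacid dehydrogenase that acts in the breakdown of lysine and tryptophan, and in people changes in this gene are linked to a form of Charcot-Marie-Tooth disease, an inherited disease of peripheral nerves. The comparison asks which transcripts of the cord differ when the gene is knocked out. The 75th percentile of the processed signal was 950 to 1055 intensity units across the 6 arrays, and 78.4% to 82.0% of spots were well above background. Across genes, which are not independent replicates, pairs of arrays correlated at r of 0.983 to 0.991. The first principal component held 31.5% of the variance with the genotypes overlapping along it, and wild-type replicate 3 at -46.8 and null replicate 1 at 36.4 at its ends.

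Dhtkd1 signal was lower in all 3 null samples than in all 3 wild-type samples at both probes of the gene on chromosome 2 (mm9). At positions 5825028 to 5825087 the log2 signal was -2.82 ± 0.36 (SD, n = 3) in wild-type and -3.89 ± 0.46 (SD, n = 3) in null samples, a log2 difference of -1.07 (SE 0.29), or 2.11-fold lower. At positions 5817910 to 5817969 it was -2.97 ± 0.09 in wild-type and -4.05 ± 0.06 in null samples, a log2 difference of -1.08 (SE 0.08), or 2.12-fold lower. Both differences were larger than the spread between replicates, and each had an exact permutation p of 0.1, the smallest that 3 against 3 arrays allow. With each kept probe fitted on its own by limma, the second probe had an unadjusted p of 1.2e-05 and the first 0.0092. No probe passed in that fit, where the lowest adjusted p was 0.0862. Among 21438 genes the first probe, which represents the gene, had an adjusted p of 0.453 by limma and did not pass. Its log2 difference was -0.78 (SE 0.40, adjusted p 0.700) with slide as a block and -0.68 with normexp background correction. Both probes remained well above background on all 6 arrays, and since the deleted part of the gene is not stated, a probe outside that part checks nothing.

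**Figure D1:**
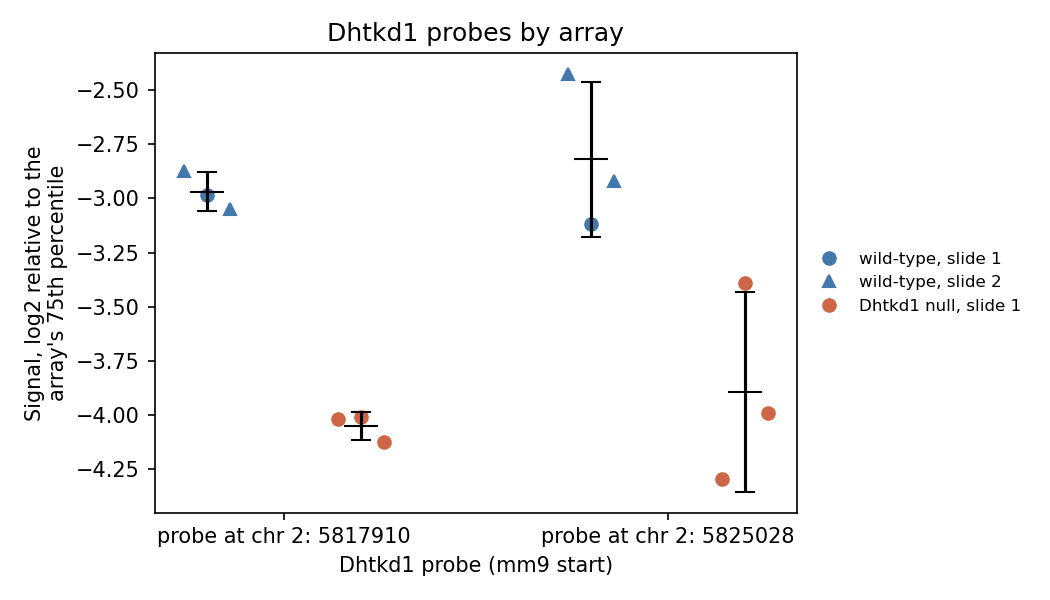
Signal of the 2 Dhtkd1 probes on each array (y axis, log2 relative to the array's 75th percentile) by probe start on chromosome 2 of mm9 (x axis). Points are arrays, with circles for slide 1 and triangles for slide 2, and bars are the group mean and SD of 3 arrays. At both probes the 3 null arrays lie below the 3 wild-type arrays, by -1.08 and -1.07 on the log2 scale between means.

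Gdpd3, Plin4 and Cyp4f15 were among the 12 genes named as higher in null samples, with the 3 null samples above the 3 wild-type samples for each, although no single gene passed the adjusted threshold. Gdpd3, which encodes a phosphodiesterase acting on lysophospholipids (probe on chromosome 7, 133914520 to 133914693), had a log2 signal of -4.03 ± 0.21 (SD, n = 3) in wild-type and -0.28 ± 0.50 (SD, n = 3) in null samples, 13.4-fold higher in null (log2 difference 3.75, SE 0.27, adjusted p 0.0910). Plin4, a coat protein of lipid droplets, was at -0.19 ± 0.33 in wild-type and 2.50 ± 0.31 in null samples, 6.46-fold higher (log2 difference 2.69, SE 0.23, adjusted p 0.106). Cyp4f15, a fatty acid hydroxylase of the cytochrome P450 family (chromosome 17, 32840088 to 32840147), was at -1.85 ± 0.08 and -0.56 ± 0.04, 2.45-fold higher (log2 difference 1.29, SE 0.07), with the lowest adjusted p of all genes, 0.0553. Cyp4f15 passed in 7 alternatives, with adjusted p of 0.0122 to 0.0438, among them the authors' value table at 0.0319 and trend and robust options at 0.0194, where Gdpd3 and Stk25 passed too.

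The remaining 9 genes of the 12 named as higher in null samples also missed the adjusted threshold, with adjusted p of 0.106 to 0.221 by limma, and for each the 3 null samples lay above the 3 wild-type samples. They were Tex12, a protein of meiotic chromosomes (log2 difference 1.64, well above background on 1 of 3 wild-type arrays), Hif3a, a hypoxia-inducible factor (1.44, with its other probes at 0.40 and 0.97, the first of similar brightness), Stfa3, a cysteine protease inhibitor (1.28), Ffar2, a receptor for short-chain fatty acids (1.19), and F2rl2, a protease-activated receptor (0.99). Fam83d differed by 0.89, Stk25, a protein kinase, by 0.71, Prss56, a serine protease, by 0.69, and Ms4a4c by 0.65.

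The 12 genes named as lower in null samples missed the threshold with adjusted p of 0.209 to 0.342, and for each the 3 null samples lay below the 3 wild-type samples. The log2 difference was -1.29 for Adamtsl2, an extracellular matrix protein, -1.20 for Tnfrsf17, a receptor of plasma cells that was well above background on 1 of 3 null arrays, and -1.09 for Suv39h2, a histone methyltransferase whose 3 dimmer probes differed by -0.91 to -0.30, and Tmc7 was at 1.70 ± 0.06 (SD, n = 3) in wild-type and 0.70 ± 0.24 in null samples, with its 2 much dimmer probes at -0.01 and -0.19. The difference was -0.83 for Akr1c14, a steroid dehydrogenase, -0.78 for Hkdc1, a hexokinase-like protein, -0.65 for Ube2t and -0.65 for Sox13, a transcription factor. Of the genes tied to interferon, Gbp8 and Irgm2, GTPases that interferon induces, differed by -0.79 and -0.62, and Ifna12, an interferon, by -0.76. Esrp1, a splicing factor of epithelial cells, was well above background on 0 of 3 null arrays and was 1.82-fold lower. On each of those arrays its signal exceeded the array's lowest signal well above background, so its lower bound equals the measured ratio.

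**Figure D2:**
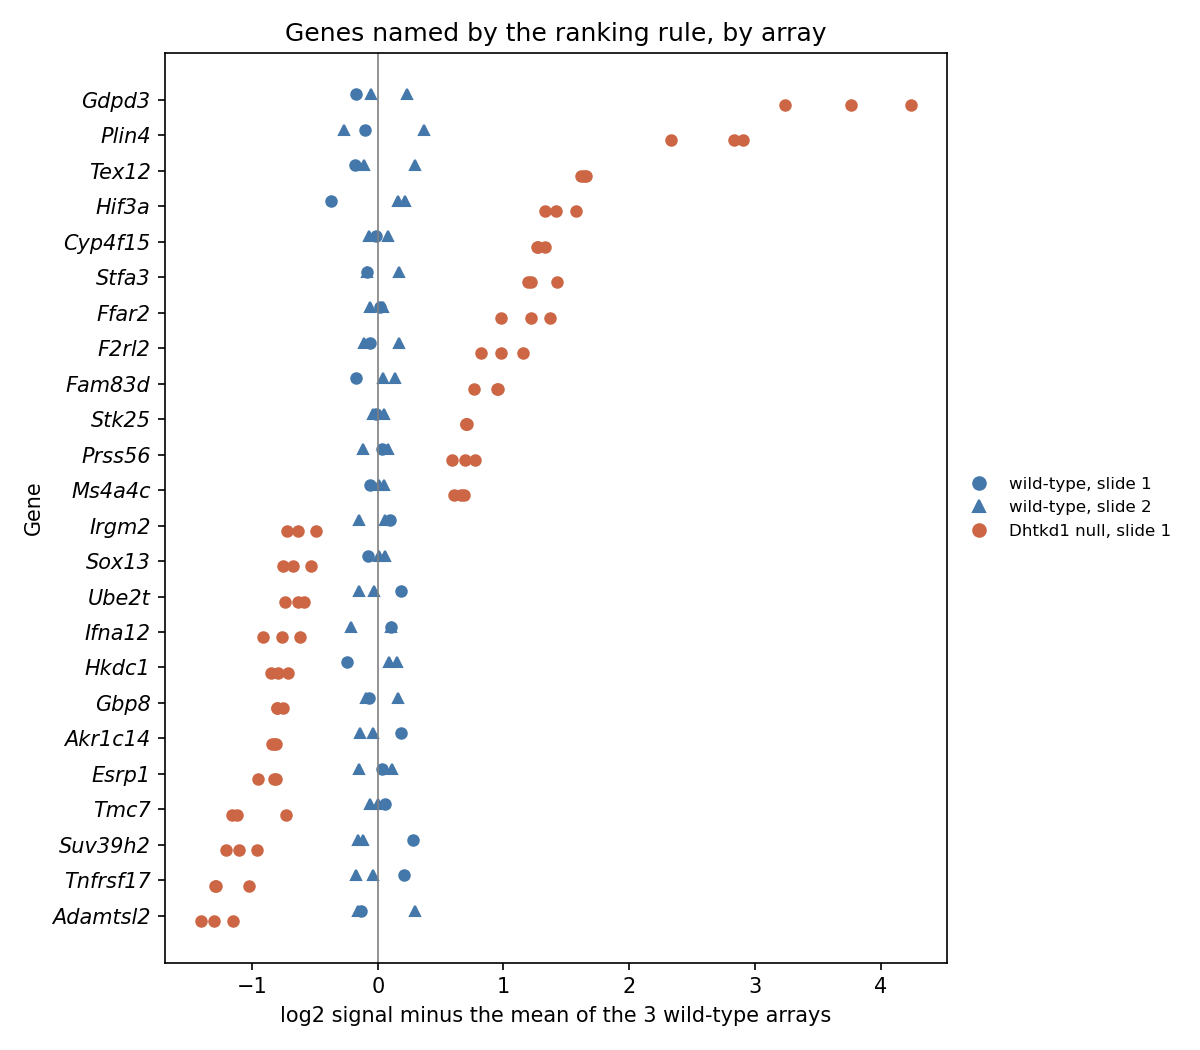
Log2 signal of each array minus the mean of the 3 wild-type arrays (x axis) for the 12 genes named as higher and the 12 named as lower in null samples (y axis). Points are arrays, coloured by genotype, with circles for slide 1 and triangles for slide 2. For each gene the 3 null arrays lie to 1 side of the 3 wild-type arrays, with Gdpd3 and Plin4 the farthest apart at mean differences of 3.75 and 2.69, and no gene passed an adjusted p of 0.05.

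By limma, 0 genes were higher and 0 were lower at an adjusted p under 0.05, against 2 higher (Cyp4f15 and Gdpd3) and 1 lower (Gm19705) under 0.1. At an unadjusted p under 0.05 there were 1931 genes, 1234 higher and 697 lower, where chance gives 1072, but wild-type replicate 1 with null replicates 2 and 3 against the other 3 samples gave more, 2000, so this count does not set the genotypes apart from another grouping. Of these, 101 genes were at least 2-fold higher and 43 at least 2-fold lower. The groups did not overlap for 14.8% of genes, where chance gives 10%. Blocking on slide, 0 genes passed the adjusted threshold, and 121 were at least 2-fold higher and 124 at least 2-fold lower. That fit rests on wild-type replicate 2 against the 3 null samples of slide 1, so the blocked differences below equal those within slide 1, and slide 2 holds wild-type samples only and gives none. The count of genes at least 2-fold higher was 168 without wild-type replicate 2, 164 without null replicate 1 and 155 without null replicate 3. Without null replicate 1, 1 gene passed the adjusted threshold as higher (Scgb3a1), and without null replicate 2, 2 passed as lower (4930520O04Rik and TC1634701).

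Of 36 gene lists, 6 rose and 10 fell in null samples by camera with the preset correlation. Of these 16 calls, 0 held with an estimated correlation (adjusted p of 0.692 to 0.959 over the 36 lists) and 0 with fry (lowest adjusted p 0.307, with 4 lists at an unadjusted p under 0.05). Blocking on slide, 12 lists passed, 9 of them among the 16 and in the same direction. Without wild-type replicate 3, 10 lists passed. With quantile normalization 11 lists passed, and 6 of the 16 calls were lost at adjusted p of 0.0682 to 0.0911: 2-oxoacid dehydrogenases and citric acid cycle, oxidative phosphorylation, Charcot-Marie-Tooth disease genes, immediate early genes, circadian clock and meningeal fibroblast. The same 6 were lost with the authors' value table (0.0679 to 0.0941). For 13 of the 16 lists the array means of the 2 genotypes overlapped. The number of list members past the adjusted threshold over all genes was 0 in every list. Adjusted over the list alone it was 8, in the 3 lists named with such members below, and 0 in the others. Mt1 and Mt2 are counted in 2 of these lists.

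Genes of cholesterol synthesis fell together: 23 of 25 were lower in null samples, 12 of them at an unadjusted p under 0.05 and 0 higher at that level. The median log2 difference was -0.36 (adjusted p 1.6e-10), with an adjusted p = 0.692 with an estimated correlation, and -0.49 (adjusted p 2.7e-10) with slide as a block. Among its members, none of which passed alone, Mvd differed by -0.64 (SE 0.20) and Lss by -0.59 (SE 0.20). The estimated correlation between its genes was 0.67, so its 25 genes are not independent. The array means overlapped, with wild-type replicate 1 (-0.03) below null replicate 1 (0.03). Wild-type replicate 2 had the highest array mean of this list (0.30) and also of the genes of oligodendrocytes, the cells that make myelin in the cord (0.34).

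Genes of oligodendrocytes and central myelin also fell, with 24 of 29 lower, a median of -0.17 (adjusted p 8.5e-04) and an adjusted p = 0.741 with an estimated correlation. With slide as a block the median was -0.47 (adjusted p 2.1e-08), without wild-type replicate 1 it was -0.32, and without wild-type replicate 2 it was -0.07 and the call was lost (adjusted p 0.129). Sox10, a transcription factor of myelinating cells, differed by -0.46 (SE 0.12) and Aspa, an enzyme of oligodendrocytes, by -0.48 (SE 0.12). Oligodendrocyte precursor genes did not pass, with 6 of 8 lower (adjusted p 0.0662, and 0.0332 without wild-type replicate 1). Their members of smallest p were Gpr17 at -0.48, whose dimmer probe differed by 0.06, and Cspg4 at -0.17.

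Charcot-Marie-Tooth disease genes fell slightly, with 33 of 44 lower and a median of -0.06 (adjusted p 0.0202, and adjusted p = 0.692 with an estimated correlation). The call was lost with slide as a block (median -0.06, adjusted p 0.0824), without wild-type replicate 3 (0.0812) and without null replicate 3 (0.0733). With median centring the median was -0.10 (adjusted p 0.0153). Lmna differed by -0.31 and Trpv4, a cation channel, by 0.53. Schwann cell and peripheral myelin genes did not pass, with 12 of 15 lower and a median of -0.29 (adjusted p 0.0662). They did pass without wild-type replicate 2 (5.2e-04), null replicate 2 (0.00911) or null replicate 3 (0.0112), and the median was 0.74 with slide as a block. Of this list, 4 genes are in another list. Pmp2, a lipid-binding protein of peripheral myelin, was well above background on 0 of 3 null arrays and at least 5.21-fold lower, a bound that rests much on wild-type replicate 1, being 3.18-fold without that sample, 8.03-fold without wild-type replicate 2 and 2.19-fold within slide 1, and Pmp22 differed by -0.77 (SE 0.60) and turned direction with slide as a block.

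Around the enzyme that was knocked out, genes of lysine and tryptophan breakdown did not pass: 9 of 27 were higher and 18 lower, with a median of -0.02 (adjusted p 0.261). Aass, the first enzyme of lysine breakdown, differed by 0.30 (SE 0.12) and Hadh by -0.23 (SE 0.10). Genes of 2-oxoacid dehydrogenases and the citric acid cycle fell by little, with 28 of 37 lower and a median of -0.04 (adjusted p 0.0268, and adjusted p = 0.741 with an estimated correlation). The median was -0.11 (adjusted p 0.00488) with slide as a block. It was -0.07 without null replicate 1 and -0.06 without null replicate 2, and the call was lost without wild-type replicate 2 (median -0.03, adjusted p 0.190) and null replicate 3 (-0.02, 0.110). With median centring it was -0.09 (adjusted p 0.0105). Sdhc, a subunit of succinate dehydrogenase, differed by -0.27 and Suclg2 by -0.33, with a second probe of similar brightness at -0.03.

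Genes of oxidative phosphorylation fell by a median of -0.03, with 55 of 70 lower (adjusted p 0.0190, and adjusted p = 0.809 with an estimated correlation), and with slide as a block by a median of -0.10 (adjusted p 4.0e-05). The median was -0.08 without wild-type replicate 3 and -0.05 without null replicate 1. The call was lost without wild-type replicate 1 (-0.03, adjusted p 0.0513), wild-type replicate 2 (-0.01, 0.367) and null replicate 3 (-0.01, 0.161). It was -0.08 (adjusted p 6.7e-04) with median centring, so the size of a shift this small depends on the normalization, where the median of all genes was 0.017. Its members of smallest p were Cyc1 at -0.13 and Ndufb9 at -0.14. Genes of mitochondrial biogenesis and dynamics did not pass, 11 higher and 11 lower (adjusted p 0.603), led by Yme1l1 at 0.16 and Pink1 at -0.13. Neither glycolysis, with 10 of 17 higher and a median of 0.04 (adjusted p 0.317; Ldha 0.39, Pfkl 0.27), nor insulin signalling and its target genes, with 16 of 27 higher (adjusted p 0.799), passed. In the insulin list, Slc2a1, a glucose transporter, differed by 0.47 and Tbc1d4 by 0.39, with a dimmer probe of Tbc1d4 at -0.03.

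Glucocorticoid-induced genes rose, with 10 of 13 higher, a median of 0.41 (adjusted p 5.3e-05) and an adjusted p = 0.692 with an estimated correlation. The median was 0.29 (adjusted p 1.7e-04) with slide as a block. Every null array had a higher mean over this list than every wild-type array, 0.27 to 0.34 against -0.48 to -0.09. Over all genes 0 members passed, and adjusted over the list alone 5 passed, each higher: Plin4, Cdkn1a (0.61), an inhibitor of the cell cycle, the metallothioneins Mt2 (0.41) and Mt1 (0.46), and Lcn2 (2.30), a protein of the acute phase and of neutrophil granules. A much dimmer second probe of Mt1 differed by -0.18. Of the 13 genes of this list, 3 are in another list. Fkbp5 and Pdk4, members of the list that glucocorticoids induce in many tissues, differed by 0.09 and -0.02. The array means of adipocyte and of blood and marrow leukocyte genes, given below, were highest in null replicate 2, at 1.88 and 1.07. In null replicate 3 these means were -0.77 and -0.48, while its glucocorticoid mean was 0.34, as in null replicate 2.

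Interferon response genes fell, with 18 of 24 lower, 7 of them at an unadjusted p under 0.05, and a median of -0.20 (adjusted p 3.7e-05), with an adjusted p = 0.692 with an estimated correlation. With slide as a block the median was -0.34. Without wild-type replicate 2 it was -0.06 and the call held (adjusted p 0.00118 by camera), as it did with each other array left out. The array means of this list did not overlap, at -0.15 to -0.06 in null and -0.04 to 0.22 in wild-type samples. Ifit3 differed by -0.44 (SE 0.09), Gbp3 by -0.38 (SE 0.09) and Bst2 by -0.53, all 3 induced by interferon. Microglia and macrophage genes rose, with 16 of 19 higher and a median of 0.19 (adjusted p 0.0268, and adjusted p = 0.741 with an estimated correlation), and Fcrls and C1qb differed by 0.82 and 0.58. That call was lost with slide as a block (median 0.08, adjusted p 0.380) and without wild-type replicate 1 (0.12, 0.455), null replicate 2 (0.17, 0.0943) or null replicate 3 (0.23, 0.0645), and the median was 0.35 without wild-type replicate 2 and 0.33 without wild-type replicate 3.

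The stress lists did not pass. Oxidative stress genes were 7 higher and 12 lower (adjusted p 0.821), and Mt1 and Mt2 passed adjusted over the list alone. Protein folding stress genes were 20 higher and 7 lower (adjusted p 0.289, but 0.0169 without wild-type replicate 3 and 0.0311 without null replicate 1). Among these, Cryab, a small heat shock protein, differed by -0.73 and Sdf2l1 by 0.41. Amino acid and integrated stress response genes were 12 higher and 13 lower (adjusted p 0.944), with Mthfd2 at 0.31 and Chac1 at 0.23. The median, mean and test differed in sign for 4 lists, all far from the threshold: mitochondrial biogenesis and dynamics, astrocyte, insulin signalling, and amino acid and integrated stress response.

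Genes of glutamate, GABA and glycine transmission rose, with 33 of 40 higher and a median of 0.10 (adjusted p 0.00668, and adjusted p = 0.741 with an estimated correlation). Glra3, a glycine receptor subunit, differed by 0.62 and Grin2b, a glutamate receptor subunit, by 0.39. With slide as a block the median was 0.10 (adjusted p 0.00327), with median centring 0.048 (0.00718) and with every kept probe on its own 0.18 (1.4e-06). Without wild-type replicate 1 it was 0.16, and the call was lost without wild-type replicate 3 (0.05, adjusted p 0.176) and null replicate 1 (0.09, 0.0511). Neuron genes, of which 7 of 20 are in another list, rose as well, with 14 of 20 higher and a median of 0.12 (adjusted p 0.0317, and adjusted p = 0.741 with an estimated correlation), and 0.16 (adjusted p 0.00327) with slide as a block. Tac1, a neuropeptide precursor, differed by 0.46 and Camk2a by 0.59. This call was lost without wild-type replicate 2 (0.07, adjusted p 0.190), wild-type replicate 3 (0.07, 0.153) or null replicate 1 (0.11, 0.164).

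All 6 sensory ganglion genes measured were higher in null samples, with a median of 0.77 (adjusted p 0.0200, and adjusted p = 0.741 with an estimated correlation), and null replicate 3 stood apart, with a mean over the list of 1.36 while the other null arrays were at -0.23 and -0.05 and wild-type arrays at -0.44 to -0.32. Without null replicate 3 the median was 0.20 (adjusted p 0.253), and the call was also lost without wild-type replicate 1 (0.69, 0.0508) and with slide as a block (0.69, 0.0990). Pou4f1, a transcription factor of sensory neurons, differed by 0.37 and Prokr2 by 0.97. Motor neuron genes did not pass, with 10 of 14 lower (median -0.08, adjusted p 0.113; Spp1 -0.22, Chodl -0.53), but passed without wild-type replicate 1 (0.0206) and with slide as a block (median -0.78, adjusted p 9.7e-06). Neurofilament and axon cytoskeleton genes were 8 higher and 13 lower (adjusted p 0.349; Gap43 0.34, Kif5a 0.13) and passed with slide as a block (-0.12, 0.0111). Nerve injury genes were 9 higher and 3 lower (adjusted p 0.0756, and 0.00963 without wild-type replicate 2), with Adcyap1 at 0.48 and Flrt3 at 0.31.

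Genes of meningeal fibroblasts and of ependymal cells varied widely between arrays of the same genotype. Meningeal fibroblast genes fell, with 11 of 13 lower and a median of -0.71 (adjusted p 0.0317, and adjusted p = 0.809 with an estimated correlation), but array means ran from -0.54 to 1.48 in wild-type and from -1.76 to 0.79 in null samples. The median was 0.31 (adjusted p 0.809) with slide as a block, 0.21 (0.956) without null replicate 1, -0.32 (0.821) without wild-type replicate 3, -1.23 without wild-type replicate 2 and -1.16 without null replicate 3. With wild-type replicate 3 and null replicate 1 both left out the list passed in the opposite direction (0.78, adjusted p 0.00502). Lum and Col1a1, matrix proteins, differed by -1.42 (SE 0.75) and -1.23 (SE 0.72). Ependymal cell genes fell, with 8 of 9 lower and a median of -0.42 (adjusted p 0.0268, and adjusted p = 0.741 with an estimated correlation), led by Foxj1 at -0.33 and Rsph1 at -0.40. That call was lost with slide as a block (0.043, adjusted p 0.940) and without wild-type replicate 1 (-0.21, 0.308), wild-type replicate 3 (-0.42, 0.0625) or null replicate 1 (-0.21, 0.367), and the median was -0.72 without wild-type replicate 2.

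All 7 red blood cell genes measured were higher in null samples, with a median of 0.71 (adjusted p 0.0362, and adjusted p = 0.741 with an estimated correlation), and 0.97 (adjusted p 8.1e-05) with slide as a block. Without wild-type replicate 2 the median was 0.36 (adjusted p 0.388), without null replicate 1 it was 0.57 (0.216), and it was 0.44 without wild-type replicate 3 and 0.47 without null replicate 2. Alas2, an enzyme of haem synthesis, differed by 0.72 and Hbb-bt by 0.42. Blood and marrow leukocyte genes did not pass, with 10 of 14 higher (median 0.91, adjusted p 0.105, but 4.0e-04 without null replicate 3). Ms4a1, of B cells, differed by -2.03, with 1 of 3 null arrays well above background, and Elane, of neutrophil precursors, by 2.31 (SE 0.98), with 2 of 3 wild-type arrays well above background. Skeletal muscle genes were 15 of 16 higher (adjusted p 0.0662; Actn3 0.91, Atp2a1 1.07), but passed as higher at 2.1e-09 without wild-type replicate 2 and at 0.0108 to 0.0297 in 6 other alternatives: quantile normalization, median centring, normexp, the authors' value table, every kept probe on its own and replicate number as a block. They turned to a median of -0.69 (3.8e-05) with slide as a block. Adipocyte genes were 7 of 8 higher (adjusted p 0.422; Ucp1 1.78, SE 1.17, Retn 0.70), and passed without wild-type replicate 2 (0.0472), without null replicate 3 (0.0481) and with replicate number as a block (0.0249), while the median turned from 0.79 to -0.81 (adjusted p 0.203) with slide as a block.

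Endothelial and mural cell genes did not pass, with 5 higher and 11 lower (adjusted p 0.288, and 0.0458 without wild-type replicate 2). Ly6c1 (0.85, SE 0.15), a surface protein of endothelial cells and monocytes, passed adjusted over the list alone, and Slco1a4, a transporter of the blood-brain barrier, differed by -0.34. Astrocyte genes were 9 higher and 7 lower (adjusted p 0.614; Sox9 -0.29, Agt 0.26), and cytosolic ribosomal proteins 49 higher and 28 lower (adjusted p 0.741; Rps13 -0.22, Rpl27a 0.19), whose test turned direction with median centring.

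Circadian clock genes fell, with 14 of 19 lower and a median of -0.10 (adjusted p 0.0317, and adjusted p = 0.741 with an estimated correlation). Dbp, a clock output gene, differed by -0.52 and Ciart by -0.44. The median turned to 0.032 (adjusted p 0.308) with the mean of all kept probes of a gene and was -0.0051 (0.313) with every kept probe on its own, so the call rests on the choice of probe. It was also lost with slide as a block (-0.013, adjusted p 0.940) and without wild-type replicate 1 (-0.04, 0.0994), wild-type replicate 3 (-0.07, 0.272) or null replicate 3 (-0.07, 0.0645). Immediate early genes fell, with 15 of 21 lower and a median of -0.17 (adjusted p 0.0374, and adjusted p = 0.741 with an estimated correlation). Ccn1 differed by -0.95 and Ier3 by 0.62. This call was lost with slide as a block (-0.10, adjusted p 0.285) and without wild-type replicate 3 (-0.09, 0.221) or null replicate 1 (-0.11, 0.367).

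Genes near Dhtkd1 on chromosome 2 did not pass as a list, with 18 of 28 lower (adjusted p 0.0662), led by Sephs1 at -0.33 (SE 0.09), with a second probe of similar brightness at -0.03, and Nudt5 at 0.24. Suv39h2, at 3381885 to 3381944 of the same chromosome, is not in that list but lies within 10 Mb of Dhtkd1. Substrain genes, which differ between sublines of the strain, were 1 higher and 4 lower (adjusted p 0.301), with Entpd4 at -0.23, its second probe at 0.04, and Gabra2 at -0.29. Gabra2 and Wdfy1, also of this list, were lowest in wild-type replicate 3 and null replicate 1 (Gabra2 0.94 and 0.51, other samples 1.17 to 1.48). Nnt, Entpd4 and Ide did not split this way. A test between genotypes cannot detect such a split.

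**Figure D3:**
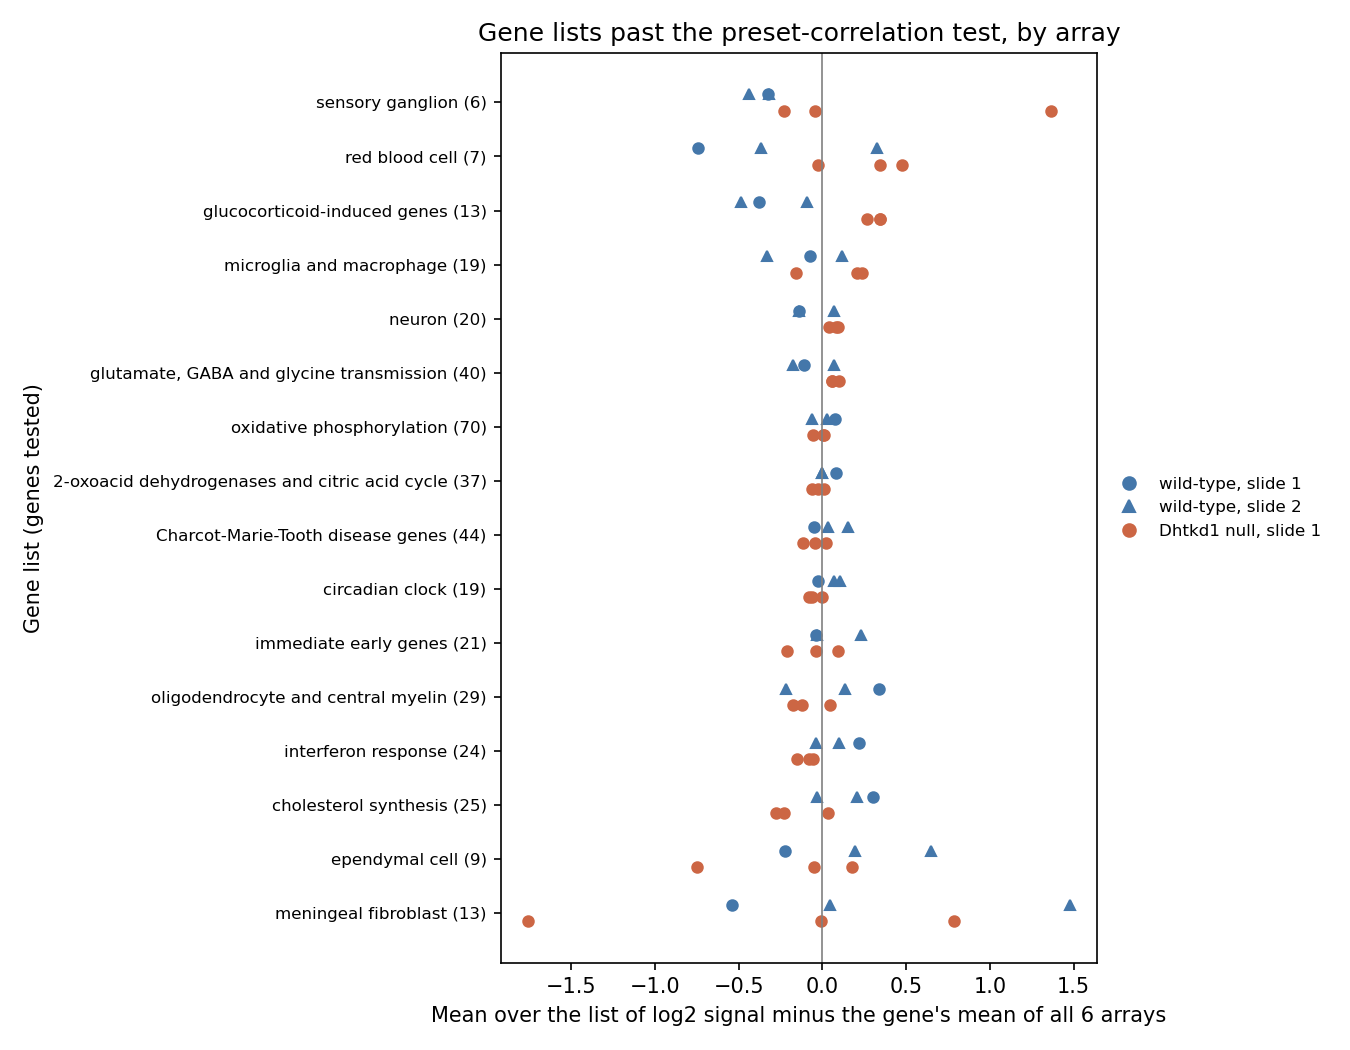
Mean over each list's tested genes of the log2 signal minus the gene's mean of all 6 arrays (x axis) for the 16 lists past camera with the preset correlation (y axis, with the number of genes tested). Points are arrays, coloured by genotype, with circles for slide 1 and triangles for slide 2. Genotypes overlap in 13 of the 16 lists, the 3 null arrays lie above the 3 wild-type arrays for glucocorticoid-induced genes (0.27 to 0.34 against -0.48 to -0.09), and 1 null array at 1.36 stands apart for sensory ganglion genes.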

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

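Alternatives were planned before the data were examined, except the 4-array one, chosen after seeing the data. Dhtkd1, taken as 1 representative probe or as the mean of its probes, was lower in each and past the threshold in none. Its difference was -1.33 to -0.87 with 1 array left out and -1.07 (adjusted p 0.574 by limma) with replicate number as a block. Higher genes, 0 in the fit reported, were 2 at an adjusted p under 0.1, 1 with quantile normalization, median centring, normexp, the authors' value table, a filter on all arrays or array weights, 3 with trend and robust options, 0 to 1 with 1 array left out and 0 in the others. Lower genes were 1 under 0.1, 0 to 2 with 1 array left out and 0 in the others. At least 2-fold higher were 32 with normexp, 178 with no filter, 201 in the 4-array alternative and 88 to 168 with 1 array left out. At least 2-fold lower were 10, 88, 124 with slide as a block and 121 on slide 1 alone. Lists past the threshold were 0 with an estimated correlation, 0 with fry, 10 to 16 with 1 array left out and 11 to 21 elsewhere, the 21 with replicate number as a block. More or fewer probes tested is part of the filter settings; for the other changes the cause was not tested.

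Among the 16 lists past the threshold, median differences that turned were meningeal fibroblast (0.31 with slide as a block and on slide 1 alone, 0.78 in the 4-array alternative, where the list passed as higher at an adjusted p of 0.00502, 0.21 without null replicate 1), ependymal cell (0.043 in both slide settings) and circadian clock (0.032 with the mean of a gene's probes, where the test kept its direction). Of the other 20 lists, medians that turned with slide as a block were Schwann cell and peripheral myelin (0.74), skeletal muscle (-0.69), adipocyte (-0.81), endothelial and mural cell (0.050), astrocyte (-0.19), glycolysis (-0.0091) and cytosolic ribosomal proteins (-0.0043). The test of circadian clock turned on slide 1 alone (median -0.013). Of 95 named genes other than Dhtkd1 (88 with a filter on all 6 arrays), 4 turned in each slide setting (Pmp22, Actn3, Atp2a1 and Ucp1) and 0 elsewhere. Of 36 lists the test turned in 9 with slide as a block and 10 on slide 1 alone. It turned in 1 to 6 lists with 1 array left out, the 6 without null replicate 3, and in 0 to 2 in the other settings. As to pairing, deviations of equal replicate numbers correlated across genes at -0.02, -0.11 and 0.33, and of different numbers at -0.24 to 0.27. Differences of dim genes are limited by signal over background, and normexp, whose offset draws dim signals together, gave fewer 2-fold genes.

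Calls not lost could still change in size. With median centring the median was -0.087 for 2-oxoacid dehydrogenases and citric acid cycle, -0.081 for oxidative phosphorylation, -0.10 for Charcot-Marie-Tooth disease genes, 0.048 for glutamate, GABA and glycine transmission and 0.070 for neuron. With normexp it was 0.26 for sensory ganglion and 0.46 for red blood cell, and with every probe on its own -0.096 for interferon response. Meningeal fibroblast was at -0.46 with the mean of a gene's probes and with every probe on its own. Median centring lost immediate early genes (adjusted p 0.0852) and meningeal fibroblast (0.125). Normexp lost 2-oxoacid dehydrogenases and citric acid cycle, oxidative phosphorylation, immediate early genes, circadian clock and meningeal fibroblast (0.0697 to 0.0949). The 4-array alternative lost Charcot-Marie-Tooth disease genes, glutamate, GABA and glycine transmission, immediate early genes, circadian clock, neuron, ependymal cell and red blood cell (0.103 to 0.871), and turned meningeal fibroblast. Array weights lost immediate early genes, circadian clock, meningeal fibroblast, ependymal cell and red blood cell (adjusted p 0.0502 to 0.451), and the mean of a gene's probes lost circadian clock (0.308) and neuron (0.0538).

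Lists that missed the threshold and passed in some alternatives, beyond those given with 1 array left out or slide as a block, were skeletal muscle and adipocyte as given above, nerve injury (adjusted p 0.0467 with median centring, 0.00575 with every probe on its own), blood and marrow leukocyte (0.0297 and 0.0317 in the same settings, 0.0218 with replicate number as a block), oligodendrocyte precursor (0.0301 with every probe on its own, 0.0217 with replicate number as a block), genes near Dhtkd1 (0.0447 with no filter, 0.0462 with replicate number as a block), Schwann cell (0.0415 with no filter), motor neuron (0.0481 with array weights, 0.0373 in the 4-array alternative) and protein folding stress (3.9e-04 in the 4-array alternative).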

Other observations

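The tests of contamination, slide, oligodendrocyte share and chromosome segments below were chosen after the results they concern were seen, as were the splits for the glucocorticoid and cholesterol lists and for the count of genes at an unadjusted p under 0.05. The splits for the counts of genes past the adjusted threshold, of 2-fold genes and of lists were planned before their results were seen.

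Among the larger differences were genes known from the acute phase and from myeloid cells, chosen here after their values were seen, not tested as a group, and none past the adjusted threshold. Lcn2, Lrg1, Ptgs2, which makes prostaglandins, and Ch25h, an oxysterol enzyme that macrophages induce, differed by 2.30, 2.42, 2.37 and 2.23 on the log2 scale. Lrg1, Ptgs2 and Ch25h were lower in null replicate 1 (0.11, -4.23 and -0.95) than in null replicates 2 and 3 (2.32 and 2.45 for Lrg1), and wild-type replicate 3 reached or came near null replicate 1 for all 3 (0.18, -4.23 and -1.04), so the groups overlapped for Lrg1. The stefin cluster of chromosome 16, genes of cysteine protease inhibitors, held Stfa1 at 2.77, Cstdc5 at 2.01 and Csta1 at 1.77. Stfa1 (SE 0.57) was well above background on 2 of 3 wild-type arrays, so its difference rests on dim wild-type signal. Ly6a and Ly6c2 on chromosome 15 differed by 1.25 and 1.02, and Slfn4, a gene of myeloid cells that was well above background on 0 of 3 wild-type arrays, was at least 5.17-fold higher. Scgb3a1, a secreted protein of epithelia, differed by 4.91 (SE 1.08), with null replicate 1 at -1.29 and the other null samples at 2.67 and 2.51. Gkn3 differed by -1.81 and Pisd-ps3 by 2.40.

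Some genes split the samples into discrete levels that did not coincide with the genotype groups, also chosen after their values were seen. Wdfy1, of the substrain list, was at 0.94 in wild-type replicate 3 and 1.00 in null replicate 1, and at 2.18 to 2.33 in the other 4 samples. The clone-named gene 4930520O04Rik was at -3.83 and -3.80 in null replicates 1 and 3 but at -0.26 in null replicate 2 and -0.22 to -0.06 in wild-type samples. Adat2 was at -1.45 in null replicate 1, like the wild-type samples (-1.69 to -1.39), and at 0.69 and 0.62 in null replicates 2 and 3. Abhd1 (-0.87 against 0.61 and 0.58) and Masp2 (-2.09 against -0.69 and -0.52) divided the null samples in the same way. For 4930520O04Rik, Adat2, Abhd1 and Masp2 the second level occurred in null samples only. Each is counted among the genes at least 2-fold different at an unadjusted p under 0.05 by limma, on the strength of 2 null samples.

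Glucocorticoid-induced genes were higher in null samples (median 0.413 on the log2 scale), and that this is a state of the tissue is a hypothesis found on these same arrays. Adipose tissue carried with the cord may contribute: 2 null samples had an adipocyte mean (-0.07 and -0.77) under the highest wild-type mean (1.09) while their glucocorticoid means exceeded every wild-type one, but that mean is of wild-type replicate 2 alone, and without that sample 1 null sample lay under the highest (-0.74), so the order decides nothing. Slide cannot be told apart from genotype here, since the blocked median of 0.292 sets wild-type replicate 2 alone against the null samples. Blood leukocytes left in the tissue may contribute too, since only 1 null sample, replicate 3 (-0.48), was under the highest wild-type leukocyte mean (0.16). S100a8 and S100a9 were at 4.05 and 6.10 in null against 2.70 and 4.98 in wild-type samples. By limma, 0 of the 14 leukocyte genes were higher and 1 was lower at an unadjusted p under 0.05, so neither of these 2 reached that level. The cord samples held 13 of these 14 genes well above background on all wild-type arrays, and 0 are in another list. A response to handling or time of death was not tested, genotype stays open, and the 10 splits of the 6 samples are too few for a share under 0.05, with 1 split as large, the real one, at 0.413 and the highest other at 0.271.

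Genes of cholesterol synthesis were lower in null samples (median -0.362), and slide cannot be told apart from genotype, since the blocked median of -0.494 sets wild-type replicate 2 alone, the sample with the highest cholesterol mean, against the null samples. A smaller share of oligodendrocytes could be part of it: the cholesterol mean of each array minus its oligodendrocyte mean differed by -0.148 between genotypes (pooled SD 0.0947, exact permutation p 0.2, overlapping groups), against -0.319 for the cholesterol mean itself. The cell share and a change of the pathway within cells cannot be told apart here, because 6 arrays of whole tissue decide neither and both lists were seen to fall first. The 10 splits are too few for a share under 0.05, with 2 as large, the real one at 0.362 and the highest other at 0.406, in which wild-type replicate 1 sat with null replicates 2 and 3, not a slide grouping. Genotype stays among the open explanations.

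Genes at least 2-fold different at an unadjusted p under 0.05 lay near each other more often than shuffling gives: 27 pairs within 1 Mb in the same direction, counting only genes whose names differ in their first 3 letters, against 8.01 ± 3.08 (SD) and at most 21 in 1000 shuffles (permutation p 0.001, the smallest they can give). Chromosome segments of another strain may be a source, and the count met the threshold first set for it. Its ratio to the mean of a separate set of shuffles (8.035) was 3.36. That ratio was exceeded in other splits of the samples (up to 7.44), a comparison added after the count of 27 was seen. The split at 7.44 held 9 pairs among 54 genes, against a shuffle mean of 1.21. Segments that vary between samples could also raise the ratio in other splits, so this comparison does not count against them. Many pairs are also related genes or the same locus, such as the stefins or Gkn3 with its clone. The segments and local families therefore cannot be told apart. Within 10 Mb of Dhtkd1, 2 of 85 genes (2.35%) were in this set, against 0.665% elsewhere (1-sided Fisher's exact p 0.112), too few genes to decide whether a segment came with the knockout. The 10 splits are too few for a share under 0.05, with 4 as large, the real one at 144 genes and the highest other at 210, which set wild-type replicates 1 and 2 and null replicate 1 against the rest, not a slide grouping.

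For genes past the adjusted threshold, 10 of the 10 splits gave as many as the real 0, with 2 the highest of the others. No split can give fewer than 0, so that share was fixed in advance and decides nothing. For lists past the threshold 1 split gave as many as the real 16, the real one, with 15 the highest of the others. For genes at an unadjusted p under 0.05, 2 splits gave as many as the real 1931, with 2000 the highest of the others, in which wild-type replicate 1 sat with null replicates 2 and 3. All of these have too few splits for a share under 0.05.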
